A study of Cucumis sativus with 4 samples.

How the data were processed

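RNA was extracted from young fruits of the long-fruited cucumber line 408 and the short-fruited line 409, with 2 pooled samples per line, and poly(A)-selected RNA was made into libraries with a kit that keeps the strand, per the labels' protocols. Reads were aligned with TopHat, per the submitters' processing notes. The TopHat version, the genome build, the read counter and whether counting used the strand are not given in the sources used here, so reads of overlapping genes on opposite strands and of near-identical gene copies may be counted together. The deposited table holds RPM values, which are reads of a gene per 1000000 reads of the listed genes and are not divided by gene length. Each column sums to 1000000 within rounding, and values are given to 1 decimal. All 4 columns were matched to samples by their names, and 0 columns were left unused. The labels name no sequencing batch, and fruits of both lines were collected together, per the labels.

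The table holds no read totals. The depth of each library was estimated from the steps of the rounded RPM values up to 30 RPM, as the number of reads between 8000000 and 20000000 whose whole-read multiples best matched the frequency of each value. On simulated libraries the estimate was off by at most 0.0111%. At the estimated depth 1 read is worth 0.0724 to 0.0816 RPM, which is less than the rounding step, so whole reads could not be recovered and no count test was run. Because 1 read rounds to 0.1 RPM in every library, a gene listed at 0 had 0 reads. The floor of 3 reads given for a value of 0 covers counting error only, since no molecular identifiers were described.

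Genes with at least 1 RPM in at least 2 of the 4 libraries were tested, which kept 17391 of 20000 genes. Values were taken as log2(RPM + 1), and fold changes on this scale understate the change of low genes. The lines were compared with limma 3.58.1 in R 4.3.3 (a linear model per gene with a mean-variance trend), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are 408 minus 409. With 2 libraries per line an exact permutation test of a single gene cannot go below p = 0.333, so the p-values rest on limma's pooling of the spread across genes, which added 3.08 degrees of freedom to the 2 of each gene. The procedure was tested on simulated reads, with the fitted spread of each gene and counting error added to it. The fitted spread already includes counting error, so the simulated spread is not exactly that of these libraries. With 200 of 17230 genes changed, it called 28 of 100 genes at 2-fold and 100 of 100 at 8-fold, and 13 unchanged genes. With 4000 of 17160 genes changed, it called 88.7% of genes at 2-fold and 100% at 8-fold, and 159 unchanged genes. These simulations let genes vary independently and changed only genes with a mean of at least 5 RPM. The recovery rates therefore do not cover lower genes.

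Genes described by ID were the 2 with the largest positive and the 2 with the largest negative log2 fold change among those with an adjusted p under 0.05, no overlap between lines and a mean of at least 5 RPM in the higher line, a rule set before the data were examined. The IDs were searched in a reference table of 23999 cucumber genes of assembly Cucumber_9930_V3, in which 0 of them matched. The 38 gene lists and 9 known genes fixed in advance are defined by product names and were therefore not tested. The digit after Csa in an ID was read as the chromosome and the following number as the order along it, by the naming convention of this kind of cucumber gene ID. The share of listed genes per digit ran from 9.92% to 20.9% and ranked the 7 chromosomes in the same order as the reference table, where the shares ran from 9.95% to 19.0%. Genes with UN in place of the digit formed an eighth group of 77 tested genes. Shares per group were compared with two-sided Fisher's exact tests, and same-direction neighbours with 10000 shuffles.

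Alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 RPM, median-of-ratios and quantile scaling, a fit without the trend, the replicate number as a block, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.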

Results

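Gene expression was measured by RNA sequencing in young cucumber (Cucumis sativus) fruits of 2 near-isogenic lines, which are lines bred to share most of their genome. Line 408 bears long fruits and line 409 bears short fruits. Each line was represented by 2 biological samples, and each sample was a pool of 3 to 5 fruits of 2 to 4 cm taken from different plants. The expression table listed 20000 genes as RPM, the reads of a gene per 1000000 reads of the listed genes in its library. The estimated depth, in reads of the listed genes, was 12504000 for 408 replicate 1 and 13808000 for 408 replicate 2. It was 13753000 for 409 replicate 1 and 12256000 for 409 replicate 2. At these depths 3 reads correspond to 0.217 to 0.245 RPM. Between 19390 and 19638 genes were above 0 RPM in a library. The table identified genes by ID alone and the IDs were not paired with gene names in the sources used here, so genes are described by ID, by abundance and by the chromosome number in the ID.

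The 4 libraries were first compared with one another over the 17391 genes with at least 1 RPM in at least 2 libraries. The replicates of a line resembled each other more than libraries of different lines did. Across genes, the Pearson correlation of log2(RPM + 1) was 0.975 between the 408 replicates and 0.981 between the 409 replicates, against 0.833 to 0.947 between lines. Genes are not independent replicates, and these coefficients describe the libraries only. A difference of at least 2-fold on the log2(RPM + 1) scale was found for 474 genes between the 408 replicates and for 672 genes between the 409 replicates. Between lines the same measure gave 1797 genes for the replicate 1 libraries and 5377 genes for the replicate 2 libraries. The first principal component held 89.2% of the variance. Line 408 scored 37.2 in replicate 1 and 76.7 in replicate 2, and line 409 scored -37.8 and -76.1. Both lines were therefore separated on this component, and within each line the replicate 2 library lay farther from the other line.

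**Figure D1:**
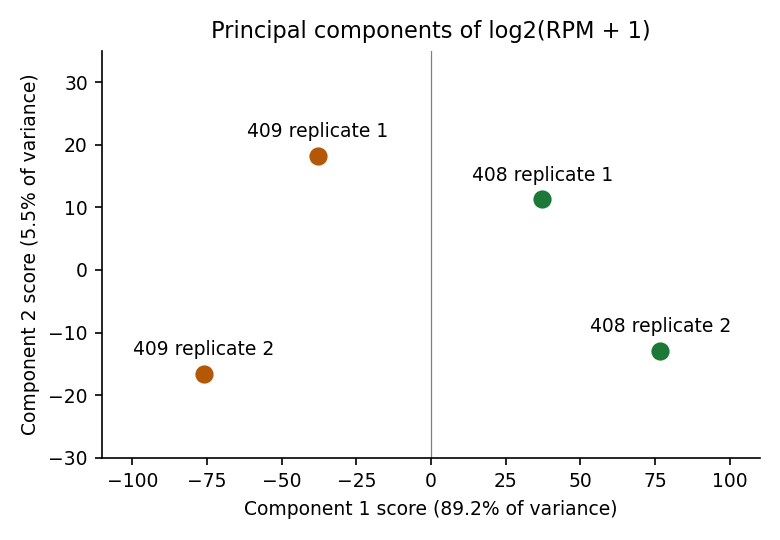
Scores of the 4 libraries on the first (x axis) and second (y axis) principal components of log2(RPM + 1), in score units, with 1 point per library, line 408 in green and line 409 in orange. The first component separates the lines, with 408 at 37.2 and 76.7 and 409 at -37.8 and -76.1.

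The long-fruited line was compared with the short-fruited line to find genes that differ between the lines. All pools held fruits of 2 to 4 cm. A relation to final fruit length cannot be told apart from other differences between the lines, including growth stage at that size. In young fruits of line 408, 2981 genes were higher and 1757 were lower than in line 409, so that 4738 of the 17391 tested genes differed (limma on log2(RPM + 1), Benjamini-Hochberg adjusted p under 0.05). The genes higher in 408 had a median log2 difference of 1.17 in size, and those lower in 408 a median of 1.03. Large differences were mostly in the direction of 408. At least 2-fold, 1881 genes were higher and 945 lower in 408. At least 4-fold, 496 were higher and 123 lower, and at least 8-fold, 153 were higher and 4 lower. After median-of-ratios rescaling, 1747 genes were higher and 1115 lower at 2-fold or more, 468 and 139 at 4-fold or more, and 135 and 5 at 8-fold or more. After quantile normalization the excess was smaller at 2-fold or more, with 1607 higher and 1326 lower, and the counts were 405 and 164 at 4-fold or more, and 119 and 5 at 8-fold or more. The genes whose values did not overlap between the lines numbered 13353, or 76.8% of those tested. For a single gene with unrelated values in 2 libraries against 2, 33.3% would be the expectation. Genes are not independent, since 1 component held 89.2% of the variance, so the share over genes cannot be tested against 33.3%.

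Genes that differed were found at all levels of abundance. Among the 4808 tested genes with a mean below 10 RPM, 987 differed, 704 of them higher in 408 and 283 lower. Among the 10065 genes from 10 to below 100 RPM, 2870 differed, 1810 higher and 1060 lower. Among the 2518 genes at 100 RPM or more, 881 differed, 467 higher and 414 lower. The balance of directions in these classes depended on the scaling of the libraries. Below 10 RPM, 71.3% of the genes that differed were higher in 408 at the deposited scaling, 66.5% after median-of-ratios rescaling and 46.3% after quantile normalization, and at 100 RPM or more the shares were 53.0%, 45.6% and 54.4%. The 100 most abundant genes of each line had 46 in common. A gene found in a single list need not differ between the lines, and the overlap between replicates of a line is not given here. Of the 154 genes in either list, 62 differed by limma at an adjusted p under 0.05, 30 higher and 32 lower in 408 at the deposited scaling, and 34 higher and 31 lower after quantile normalization. The 100 most abundant genes took 10.9% and 11.4% of the RPM in the 408 replicates 1 and 2, and 11.6% and 13.9% in the 409 replicates. A single gene accounted for 1.33% of the RPM in 409 replicate 2, against 0.429% to 0.624% for the leading gene of the other 3 libraries.

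**Figure D2:**
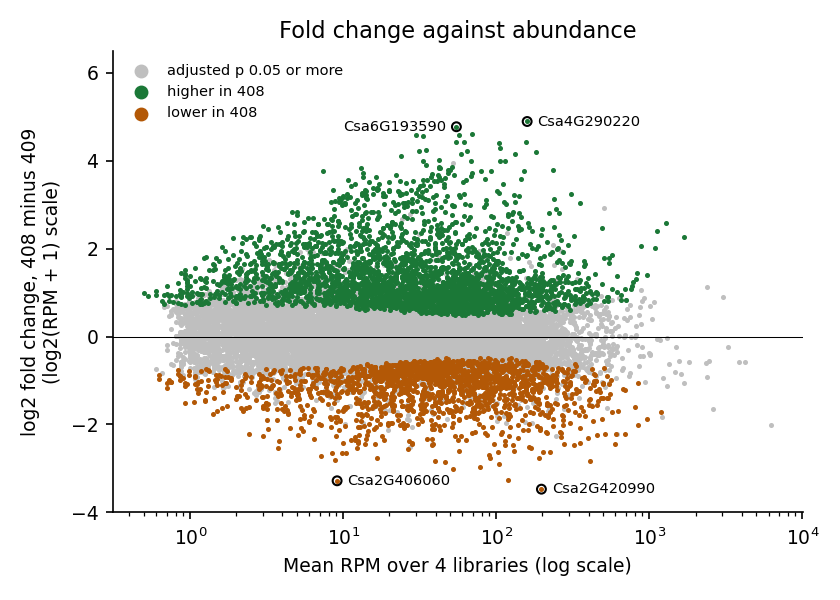
Log2 fold change of 408 minus 409 on the log2(RPM + 1) scale (y axis) against the mean RPM over the 4 libraries (x axis, log scale), with 1 point per tested gene. Genes with an adjusted p under 0.05 are green (2981 higher in 408) or orange (1757 lower in 408) at the deposited scaling (2699 and 2728 after quantile normalization), the rest are grey, and circles mark the 4 genes described by ID.

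The 2 genes with the largest differences in each direction were taken by a rule set before the data were examined. Csa4G290220 had the largest excess in the long-fruited line on the log2(RPM + 1) scale, although not by the ratio of means or at pseudocounts of 0.1 and 0.5, at 303 ± 149 RPM in 408 and 15.0 ± 18.1 RPM in 409 (mean ± SD, n = 2 per line), a 20.2-fold ratio of the means. Its log2 fold change was 4.89 with a standard error of 1.05 (limma, adjusted p = 0.0353). Its values differed widely within lines, with 198 and 408 RPM in the 408 replicates and 27.8 and 2.2 RPM in the 409 replicates, and the log2 fold change was 3.31 without 409 replicate 2 and 6.48 without 409 replicate 1. Csa6G193590 measured 106 ± 46.9 RPM in 408 and 3.9 ± 4.53 RPM in 409 (SD, n = 2 per line), a 27.1-fold ratio of the means, with a log2 fold change of 4.77 and a standard error of 0.779 (limma, adjusted p = 0.0317). Its 409 replicates measured 7.1 and 0.7 RPM, and the log2 fold change was 3.65 without 409 replicate 2 and 5.90 without 409 replicate 1. In the opposite direction, Csa2G420990 measured 31.3 ± 3.46 RPM in 408 and 362 ± 99.5 RPM in 409 (SD, n = 2 per line). It was 11.6-fold higher in the short-fruited line, and its log2 fold change was -3.47 with a standard error of 0.229 (limma, adjusted p = 0.0317). Csa2G406060 measured 0.90 ± 0.707 RPM in 408 and 17.3 ± 5.94 RPM in 409 (SD, n = 2 per line), a 19.2-fold ratio of the means, with a log2 fold change of -3.28 and a standard error of 0.371 (limma, adjusted p = 0.0317). Its 408 replicates measured 1.4 and 0.4 RPM, and the ratio was 12.4-fold without 408 replicate 2 and 43.3-fold without 408 replicate 1. Its fold change depended on the pseudocount, at -4.29 with 0.1 and -3.73 with 0.5, where it exceeded that of Csa2G420990 at -3.51 and -3.49. For all 4 genes, both libraries of one line lay above both libraries of the other, as the rule required. The functions and genome positions of these 4 genes were not analysed here.

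**Figure D3:**
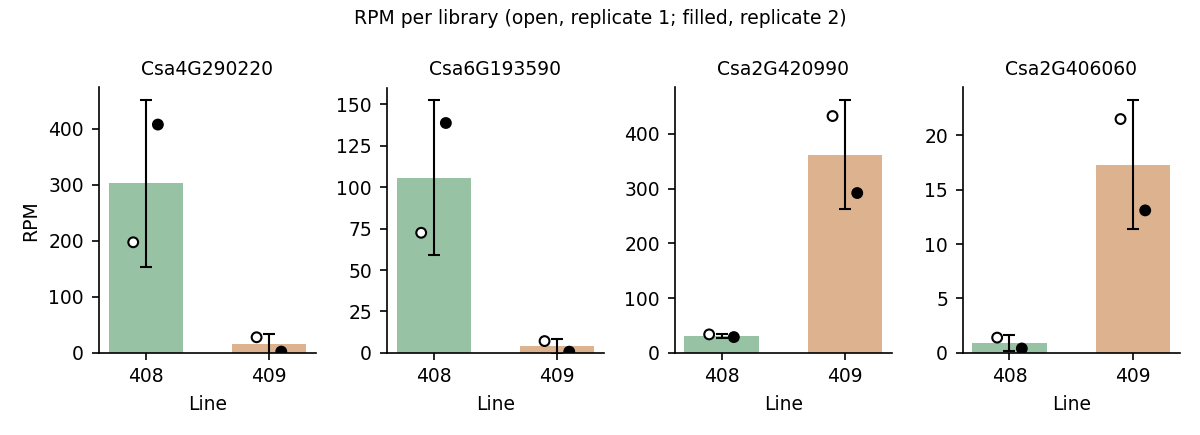
RPM (y axis, from 0) of the 4 genes described by ID in lines 408 and 409 (x axis). Bars are means, error bars are 1 SD (n = 2 per line, drawn only down to 0), open points are replicate 1 and filled points replicate 2. Csa4G290220 and Csa6G193590 are higher in both 408 libraries, and Csa2G420990 and Csa2G406060 in both 409 libraries.

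The number of genes that differ rests on a narrow margin, since the smallest adjusted p in limma was 0.0317, and it fell to 0 when no filter on low values was applied and when any 1 of the 4 libraries was left out, with 8340 genes and 3974 to 7264 genes at an unadjusted p under 0.05, respectively. The excess of genes higher in 408, 62.9% of those that differed, depended on the scaling of the libraries, at 56.4% after median-of-ratios rescaling and 49.7% after quantile normalization, where 2699 genes were higher and 2728 lower.

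No gene was exchanged completely between the lines at a substantial level. None was listed at 0 RPM in both libraries of one line and at 5 RPM or more in both libraries of the other. At 1 RPM or more, 7 genes were listed at 0 in line 409 and present in both 408 libraries, at 1.0 to 4.7 RPM, and 2 genes were listed at 0 in line 408 and present in both 409 libraries, at 1.1 to 4.5 RPM. A count of 0 reads allows a level of up to 0.217 to 0.245 RPM in these libraries, for counting error only. All 9 genes were among those tested, as a level of 1 RPM or more in both libraries of a line ensures. All 9 passed the threshold (limma, adjusted p = 0.0317 to 0.0494). They were chosen as set apart between the lines in these same libraries, so passing adds no separate evidence.

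The genes that differ were then placed by the chromosome number in their IDs, because near-isogenic lines can differ in particular chromosome segments. Genes that differed were present in all 7 chromosome groups, at 25.7% to 30.0% of the genes tested in each. The chromosome 2 group had the highest share, with 640 of 2132 genes differing, an odds ratio of 1.17 against the other genes (two-sided Fisher's exact test, adjusted p = 0.019 over 8 groups). This test counts genes as independent, which they are not, so its p-values may be too small. The chromosome 6 group followed with 827 of 2886 genes, or 28.7%, which did not pass the test (Fisher's exact test, adjusted p = 0.17). In the UN group 13 of 77 genes differed, or 16.9%, which did not pass the test either (Fisher's exact test, adjusted p = 0.161). Of the 7 chromosome groups, chromosome 7 had the lowest share, with 443 of 1721 genes. In each of the 7 groups more of these genes were higher than lower in 408, at 61.6% to 65.2% at the deposited scaling and 54.5% to 58.1% after median-of-ratios rescaling, but in only 2 of the groups after quantile normalization, at 48.5% to 51.7%. The excess of chromosome 2 was not past the threshold under 7 of the 8 other settings that called genes, with adjusted p values of 0.0667 to 0.998, and it was at 0.0496 when genes were required to reach 5 RPM.

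Neighbouring genes differed together more often than shuffled genes. In the order of the IDs, 856 pairs of neighbouring tested genes both differed in the same direction, against a mean of 688 in 10000 shuffles of the calls, a ratio of 1.24 (two-sided permutation p = 0.0002, the smallest that these shuffles can give). The ratio was 1.21 to 1.82 under the other settings that called genes. Genes are not independent replicates, and related genes that lie side by side were not separated here.

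**Figure D4:**
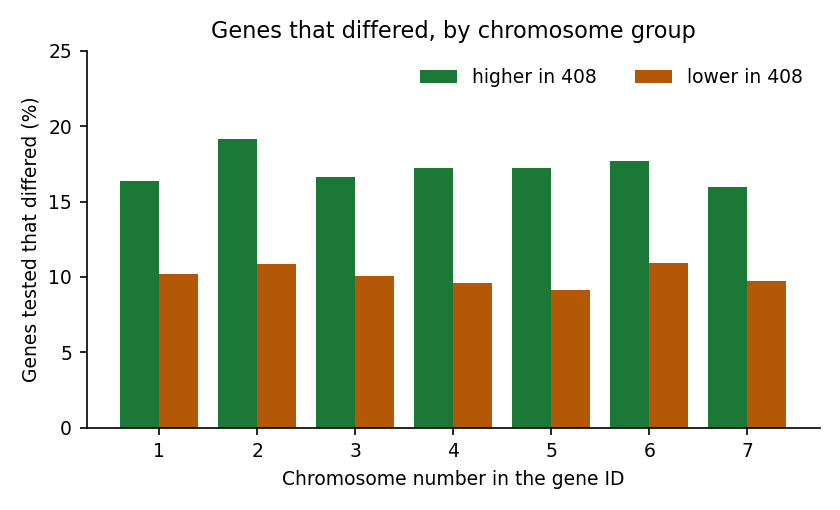
Share of the tested genes that differed between the lines (y axis, percent) for each chromosome number in the gene ID (x axis), with green bars for genes higher in 408 and orange bars for genes lower in 408. Differing genes make up 25.7% (chromosome 7) to 30.0% (chromosome 2) of each group, and green bars exceed orange bars in all 7 groups at the deposited scaling but in 2 of them after quantile normalization.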

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

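The threshold of 0.10 on the adjusted p was chosen after the data were seen, and the other settings before. The counts of 4738 genes that differ and of 2826 that differ at least 2-fold stayed within 1.5 times under both other pseudocounts, the filter of 5 RPM, both rescalings and the fit without the trend (4271 to 5427 genes, and 2582 to 2936). Without a filter on low values both counts were 0, at a smallest adjusted p of 0.0674 (limma), and the cause was not tested. Leaving out 1 library gave 0 to 0 genes for both counts, with smallest adjusted p values of 0.0633 to 0.213, in fits that assume the lone library to vary like the other line's pair and have fewer samples. In these 4 fits 2089 to 2803 of the 2826 genes stayed at least 2-fold apart, fewest without 408 replicate 2. At the 0.10 threshold 7840 genes differed. The replicate number as a block gave 1356 genes for both counts. The labels do not say that the number marks a shared batch. The deviations of same-numbered libraries correlated across genes at -0.48. This value cannot tell whether they shared a batch, because the replicate 2 libraries lay at opposite ends of the first component. Genes listed at 0 in one line rose from 0 to 9 when 1 RPM sufficed in the other. Median-of-ratios and quantile scaling moved the median log2 fold change of all genes from 0.06 to -0.01 and -0.07. The 4 genes described by ID had adjusted p values of 0.0225 to 0.245 over the 13 other settings, and their choice by non-overlapping lines fixed their direction when a library was left out. The neighbour ratio stayed past its threshold under every setting that called genes. The planned count tests on recovered reads and the gene list tests were not run, because whole reads could not be recovered and the IDs had no product names. Depth limits genes below about 0.245 RPM.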

Other observations

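The tests in this part were chosen after the results were seen, except the rescaling and the thinning of the libraries, whose bounds were set before their values were known.

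One group of genes stood out by its level in the 4 libraries. The group was chosen as the 163 genes with at least 20 RPM in 408 replicate 1 and at least 10-fold less in 409 replicate 2, a choice that works against a higher level in 408 replicate 2 and favours a lower level in 409 replicate 2 than in 409 replicate 1. Even so, 161 of the 163 genes were higher in 408 replicate 2 than in 408 replicate 1, at a median of 1.65 times (interquartile range over genes 1.5 to 1.81). In 409 replicate 1 their median was 0.196 times the level of 408 replicate 1 (0.165 to 0.243). The group made up 2.09% of the RPM in 408 replicate 2, 1.26% in 408 replicate 1, 0.296% in 409 replicate 1 and 0.0717% in 409 replicate 2. The same choice in the opposite direction gave 29 genes, of which 9 were higher in 409 replicate 2 than in 409 replicate 1. Of the genes that differed between the lines, 84.1% of those higher in 408 and 64.2% of those lower in 408 had both replicate 2 libraries at the ends. For a single gene with libraries in random order within each line, 25% would be the expectation. Genes are not independent, since 1 component held 89.2% of the variance, so these shares cannot be tested against 25%.

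Within each line the deeper library lies higher on the first component. All libraries were thinned to 12000000 reads, from reads approximated from the rounded values. Both replicate 2 libraries stayed at the ends, and the smaller of the gaps within lines kept 99.9% of its size. Thinning keeps the expected RPM of each gene, and the estimated depths of 12256000 to 13808000 reads were already close to 12000000. The gaps could therefore hardly change, and thinning cannot decide whether depth had a part in the order. Scaling by a few abundant genes is argued against as the cause of the order. After median-of-ratios rescaling both replicate 2 libraries stayed at the ends, and the smaller gap within lines kept 96.8% of its size. Mixing of material of the other line into a replicate 1 library stays open. It would give 1 mixing share for all genes. For 408 replicate 1 the 163 genes gave a median of 0.45 and 44 genes higher in line 409 gave 0.27. The difference was 0.181, with overlapping interquartile ranges. For 409 replicate 1, 29 genes higher in line 409 gave a median of -0.209 (interquartile range -0.88 to 0.0833). In that library 304 genes higher in line 408 gave 0.165 (0.125 to 0.219). These ranges did not overlap and the difference was -0.373, but the choice of genes itself produces this direction and shares below 0. The values for 409 replicate 1 therefore cannot decide. One gene programme present at a different amount in each pool, as a tissue, a cell type or a growth stage may be, also stays open, because the 98.8% of the 163 genes that were higher in 408 replicate 2 is what mixing and joint regulation by the line would give too, and the size of the fruits within the range of 2 to 4 cm was not tested.

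A second group differed between the lines and little within them. In 347 of the 3318 genes with a log2 difference of at least 1, the replicates of each line differed by less than 25% of the log2 difference between lines, and 237 of these were higher and 110 lower in 408. If a few chromosome segments that differ between the lines held most of these genes, they would gather in few places along the ID order. They fell into 212 of 352 windows of 50 tested genes, against a mean of 221 for shuffled genes (95% of shuffles between 210 and 233, one-sided permutation p = 0.0609), and at most 4 lay in 1 window, against a median of 5 in shuffles. This argues against a few segments as the location of most of these genes; an effect of such segments on genes elsewhere, and sequence differences between the lines that change how reads align, were not tested.

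The 4 libraries can be divided into 2 pairs in 3 ways. The division by line called 4738 genes with limma, and the highest of the other divisions called 0, with 6 and 31 genes at an unadjusted p under 0.05 in the other two. Only 1 of the 3 divisions reached the real count, and 3 divisions are too few for a share under 0.05. The other divisions also placed libraries of different lines in the same group. The difference between lines then widens the spread within groups, so their counts do not measure false calls.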
